A study of Eisenia andrei with 12 samples.

How the data were processed

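Gene expression was measured in Eisenia andrei, a compost earthworm widely used in soil toxicity tests. Per the labels, each biological replicate was a single sexually mature worm from its own jar, kept for 4 days in a standard test soil. The soil was treated with acetone, the solvent, or spiked with 2-phenylethyl isothiocyanate, an electrophilic compound released by cruciferous plants, at EC10 or EC50. These concentrations are named for a 10% and a 50% effect, and the labels do not say on which endpoint. There were 4 control worms, 4 EC10 worms and 4 EC50 worms, and total RNA of each was amplified, labelled with Cy3 or Cy5 and hybridised to 2 of 12 two-colour Agilent arrays.

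The labels put every worm on 2 arrays in the same dye. Worms numbered 1 and 2 carried Cy3 and worms numbered 3 and 4 carried Cy5 in all 3 groups. The arrays form 2 closed loops of 6 arrays, one with the numbers 1 and 3 and one with 2 and 4. The 12 arrays are thus 12 worms measured in overlapping pairs, and the worm was taken as the replicate (n = 4 per group).

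Per the file headers, the scanner images were read with Agilent Feature Extraction. The deposited scanner files give mean spot intensity and median local background intensity in each colour with no normalization, and processed intensities that Feature Extraction had background-subtracted, detrended and dye-normalized. The deposited log10 ratio of each spot is that of the processed Cy5 over Cy3 intensities, and it served only for this check. The authors' value table holds 1 log2 ratio per spot and array. It ran as Cy5 over Cy3, with correlations of 0.966 to 0.994 and slopes of 1.01 to 1.06 against the raw log2 ratios, and array medians of -0.0072 to 0.0116. The scale, centring and direction of the value table are thereby settled. The submitters' processing notes name limma, with no version, and the exact steps are not given in the sources used here.

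The main values came from the mean and background intensities. Background was corrected by normexp with an offset of 50, and log2 ratios were normalized by loess within each array with limma 3.58.1 in R 4.3.3. Control spots and spots with an outlier flag had weight 0, and the flags touched 1 to 22 of the 43803 probes per array. Saturated spots stayed in and numbered at most 1 per array. In each loop the 6 log2 ratios were solved by least squares for 6 worm values. Ratios carry no information on the level of one dye or loop against the other, so a worm value is relative to the 3 worms of its replicate number, which hold 1 worm of each group. A limma model with group and this replicate block was fitted to the 12 worm values, with 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A probe was tested if it was well above background on all 8 readings of at least 1 group, which left 43347 probes. The log2 intensities given for single probes come from the separate channels after loess and quantile normalization of the mean intensities, averaged over the 2 arrays of each worm.

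The median spot intensity per array was 666 to 1037 in Cy3 and 953 to 2079 in Cy5, against median local backgrounds of 21.5 to 27 and 99 to 122.5. Between 98% and 99.6% of the probes were well above background in each channel. For most probes the number of worms, not the signal, limits the precision, though some probes were dim. The 4 arrays of each pair of groups shared 1 slide, and the slide with the EC10 and EC50 pairs was scanned in a later session than the other 2. Each comparison was therefore also fitted within the slide that holds both of its groups and with a dye effect for each slide.

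The files do not pair the 43803 probes, each 60 bases long, with gene names, and no annotation was used here. The gene lists prepared for stress, detoxification, energy and tissue markers could not be matched and were not run. For the same reason, probes were named by a rule set before the data were examined: in each comparison, the 2 higher and the 2 lower probes with the smallest p, said not to pass where they do not. The sequences given are those of the array probes.

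The steps were tested on simulated data. Worm values with the measured spread of all 43347 probes were drawn, 50 probes of each size were changed and the array ratios were rebuilt with the measured technical error. In the simulated EC50 vs control comparison, the limma model on worms recovered 0 of 50 probes changed by 0.5 and 18 of 50 changed by 1 on the log2 scale, 36 of 50 changed by 2 and 38 of 50 changed by 3, with 4 false calls. With 12 arrays as replicates it made 467 false calls in the same simulation, and 234 where nothing had changed. In the simulated EC10 vs control comparison the worm model made 10 false calls. It recovered 0, 17, 43 and 47 of 50 probes there, by rising size of change. In the simulated EC50 vs EC10 comparison it made 5 false calls. The probes were drawn independently, which the real probes are not, so these numbers of false calls need not hold for the data. The alternatives set before the data were examined were the background correction, the normalization, the dim-probe filter, outlier spots, slide, block, unit of replication, the groups in the model, the authors' value table and leaving out each worm. Centring on the spike-in transcripts, 1 value per group of probes that share 30 bases, and the fits within a slide were added after the data were seen.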

Results

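The transcriptomes of 12 earthworms, 4 from solvent control soil, 4 from soil with 2-phenylethyl isothiocyanate at EC10 and 4 at EC50, were compared on 12 two-colour arrays after 4 days of exposure. Each worm was read on 2 arrays, and 43347 probes were tested. The design asks which transcripts respond to the compound at each concentration and whether the concentrations differ. Hybridisation error was small beside the residual spread between worms. The sum of log2 ratios around a closed loop, which is 0 but for hybridisation error, gave a technical SD of 0.0562 per ratio. The median residual SD between worms of a group was 0.301. It also holds any error in the amplification or labelling of a worm's RNA that its 2 arrays share, which the loop sum cannot see. Exchanging 2 arrays that enter this sum with opposite signs, in 18 ways, raised the loop error to between 0.307 and 0.594. The layout given by the titles thus had the smallest error of those tried. Exchanges of 2 arrays with the same sign leave the sum unchanged, so the check cannot see them.

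At EC10, the probes with the smallest p were higher than in control in all 4 replicate blocks. TA1-202343 (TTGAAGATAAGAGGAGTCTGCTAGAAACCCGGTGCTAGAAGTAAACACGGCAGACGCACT) had a log2 intensity of 13.49 ± 0.35 (SD, n = 4) in EC10 worms and 11.68 ± 0.24 (SD, n = 4) in controls. Its log2 change was 1.88 ± 0.18 (SE), a 3.67-fold difference. TA1-174563 (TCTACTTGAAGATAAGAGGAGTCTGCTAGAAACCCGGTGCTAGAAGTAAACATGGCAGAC), which overlaps it in sequence, differed by 1.88 ± 0.19 (SE). The limma adjusted p was 0.096 for both, so neither passed the threshold. On the lower side, TA1-026248 (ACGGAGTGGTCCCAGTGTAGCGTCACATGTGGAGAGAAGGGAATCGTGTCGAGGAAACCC) had a log2 intensity of 14.59 ± 0.47 (SD, n = 4) at EC10 and 16.02 ± 0.29 (SD, n = 4) in controls. Its log2 change was -1.58 ± 0.19 (SE), with a limma adjusted p of 0.19. TA2-093018 (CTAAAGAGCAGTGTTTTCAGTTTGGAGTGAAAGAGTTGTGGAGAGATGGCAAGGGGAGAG) differed by -1.21 ± 0.20 (SE), with a limma adjusted p of 0.41. Both were lower in 4 of 4 blocks.

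Across all probes, limma called 0 probes between EC10 and control, and 2166 probes (5%) had an unadjusted p under 0.05. Of these, 1050 were higher and 1116 were lower at EC10, against 1802 and 174 when centred on the spike-in transcripts. The change had one sign in all 4 blocks for 12.5% of the probes, and chance alone gives 12.5%. The median absolute log2 change was 0.156, against a median standard error of 0.208. With arrays in place of worms as replicates, limma called 278 probes, and with 24 channels as replicates 3642. Separate-channel worm means without the replicate block gave 4 calls and with it 0. Without control replicate 3 there were 3 calls. With each worm left out in turn, TA1-202343 had a limma adjusted p of 0.11 to 0.44 at EC10. Over 16 settings other than leaving out a worm, it passed in 3 and reached 0.93 in the model of only these 2 groups.

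**Figure D1:**
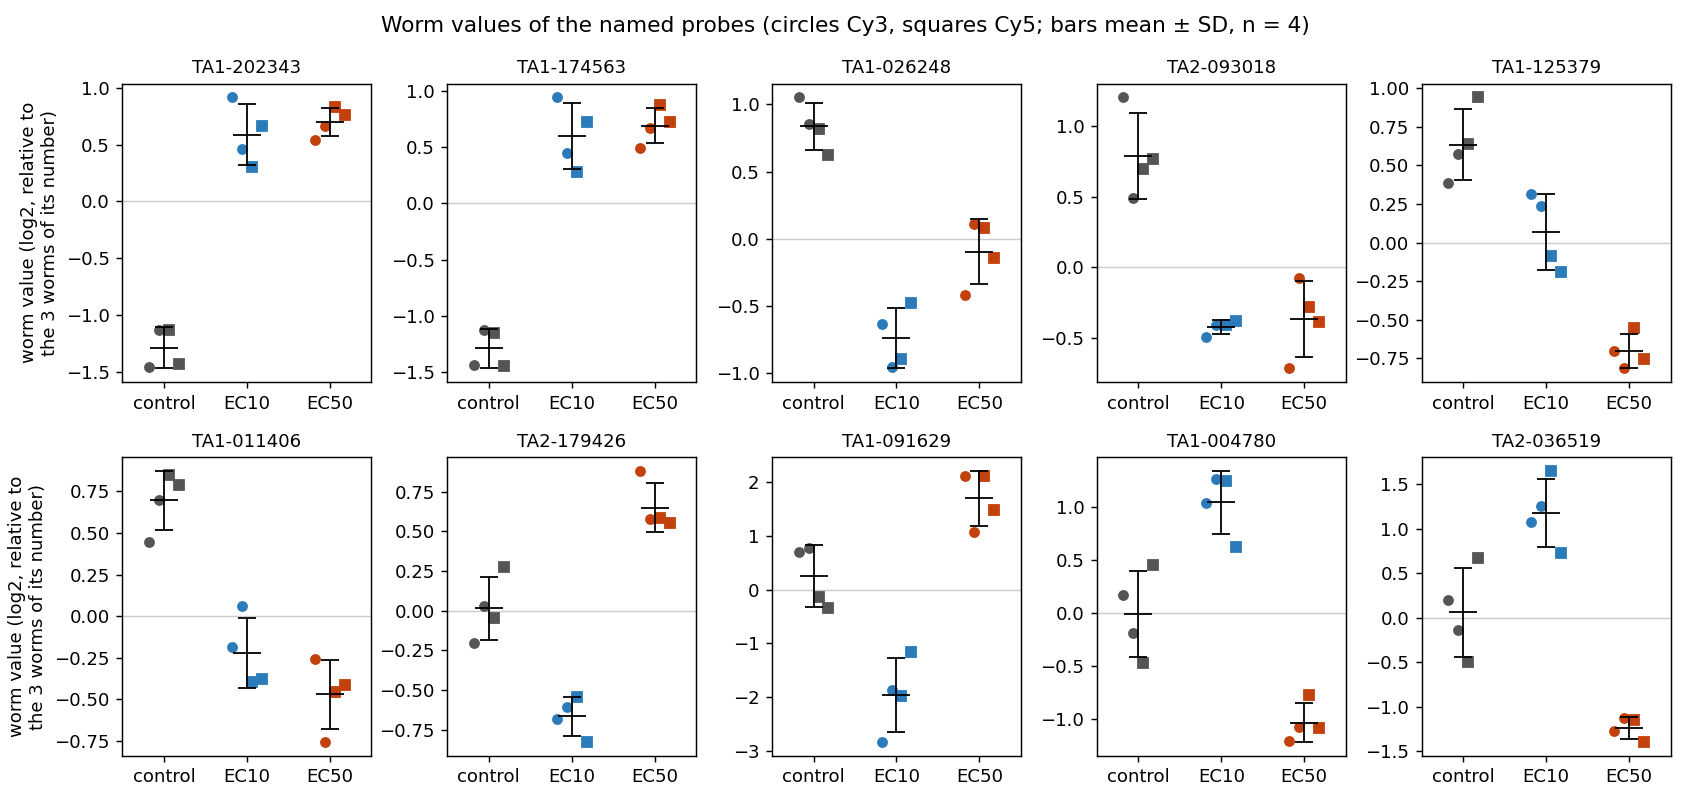
Worm values (log2, relative to the 3 worms of the same replicate number) of the 10 named probes, by group, with circles for Cy3 and squares for Cy5 and bars for the mean ± SD (n = 4). TA1-202343 and TA1-174563 lie higher in all exposed worms than in all controls, and TA1-091629 lies lowest at EC10 and highest at EC50.

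At EC50, the same 2 overlapping probes had the smallest p. TA1-202343 had a log2 intensity of 13.59 ± 0.17 (SD, n = 4) against 11.68 ± 0.24 (SD, n = 4) in controls, a log2 change of 1.99 ± 0.18 (SE) or 3.97-fold. TA1-174563 differed by 1.98 ± 0.19 (SE). Both were higher in 4 of 4 blocks, with a limma adjusted p of 0.082. On the lower side, TA1-125379 (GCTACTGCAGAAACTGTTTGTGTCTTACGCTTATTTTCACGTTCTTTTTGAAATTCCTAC) had a log2 intensity of 11.03 ± 0.26 (SD, n = 4) against 12.49 ± 0.23 (SD, n = 4), a log2 change of -1.34 ± 0.18 (SE) with a limma adjusted p of 0.16. TA1-011406 (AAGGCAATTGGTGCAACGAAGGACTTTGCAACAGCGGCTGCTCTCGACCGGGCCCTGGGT) differed by -1.17 ± 0.18 (SE), with a limma adjusted p of 0.20. Both were lower in 4 of 4 blocks. TA1-026248, named at EC10, had a smaller difference of -0.93 ± 0.19 (SE) at EC50, with a limma adjusted p of 0.25.

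Limma called 0 probes between EC50 and control, but the unadjusted p-values lay far from an even spread. An unadjusted p under 0.05 was found for 5365 probes (12.4%), 2682 higher and 2683 lower. The change had one sign in all 4 blocks for 21.8% of the probes, against 12.5% by chance. The median absolute log2 change was 0.211. With 12 arrays as replicates limma called 5524 probes, with 24 channels 10180, and with separate-channel worm means without the replicate block 25. Without control replicate 3 it called 379 probes, 77 higher and 302 lower, TA1-202343 among them with a limma adjusted p of 0.022. With each worm left out in turn, the limma adjusted p of this probe at EC50 ran from 0.022 to 0.6. Over 16 settings other than leaving out a worm, it passed in 4 and reached 0.27 in the model of only these 2 groups. The unadjusted count was 3437 without control replicate 1, 3396 without control replicate 4 and 3530 without EC50 replicate 1. Centring on the spike-in transcripts, which shifts the median of all probes by 0.56 (log2) at EC50 and 0.22 at EC10, gave 80 calls, all higher, and 17452 higher against 323 lower probes at an unadjusted p under 0.05. With it, TA1-125379 differed by -0.78 and TA1-011406 by -0.61 (log2). All other changes given here are relative to the median probe.

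**Figure D2:**
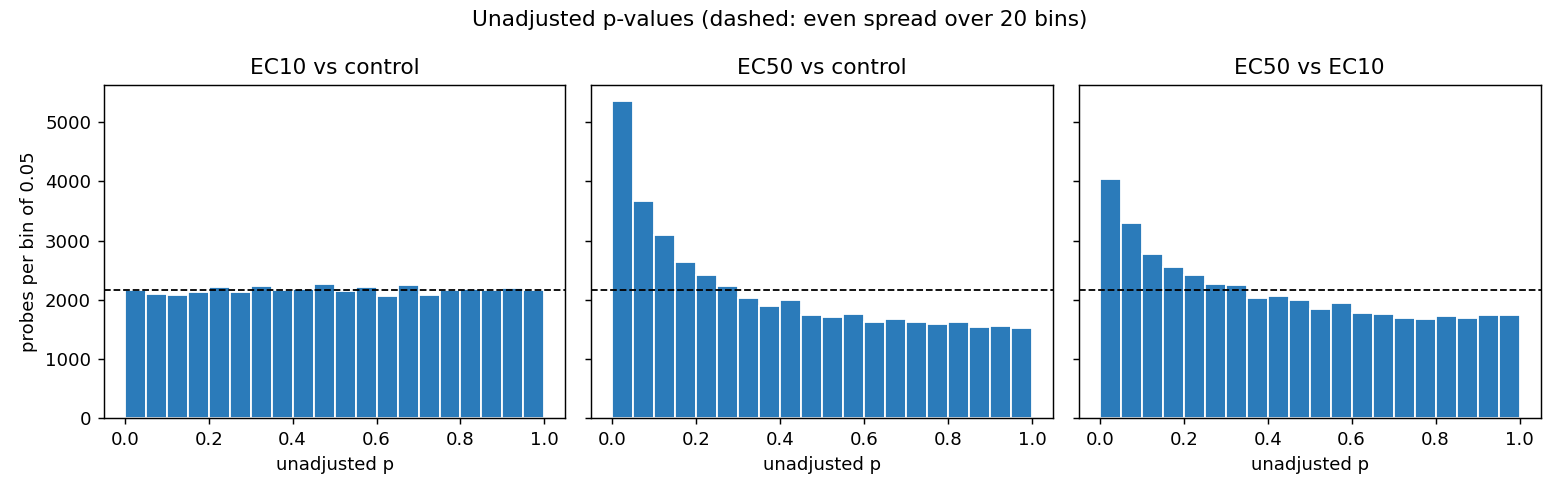
Number of probes per 0.05-wide bin of unadjusted p in each comparison, with a dashed line at an even spread over 20 bins. EC10 vs control follows the line, with 2166 probes in the first bin, while EC50 vs control and EC50 vs EC10 reach 5365 and 4041 there.

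Between the exposures, the named probes lay on opposite sides of control. TA1-091629 (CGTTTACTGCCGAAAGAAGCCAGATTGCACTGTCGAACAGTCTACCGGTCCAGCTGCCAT) had a log2 intensity of 14.01 ± 1.21 (SD, n = 4) at EC50, 12.44 ± 0.62 (SD, n = 4) in controls and 10.37 ± 0.92 (SD, n = 4) at EC10. The EC50 vs EC10 change was 3.65 ± 0.45 (SE), a 12.6-fold difference. TA2-179426 (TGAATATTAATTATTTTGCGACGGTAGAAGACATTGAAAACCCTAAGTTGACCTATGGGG) was 1.31 ± 0.16 (SE) higher at EC50 than at EC10. On the lower side, TA1-004780 (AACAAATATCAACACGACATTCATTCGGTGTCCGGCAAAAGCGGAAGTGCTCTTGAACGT) differed by -2.08 ± 0.25 (SE) and TA2-036519 (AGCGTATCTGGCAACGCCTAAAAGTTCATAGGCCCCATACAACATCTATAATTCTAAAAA) by -2.41 ± 0.29 (SE). They were well above background on 5 and 7 of the 8 readings of EC50 worms, and Agilent's processed signals gave -3.35 and -3.46, so the size of these 2 differences is uncertain. Each of these 4 probes kept its direction in 4 of 4 blocks, and each had a limma adjusted p of 0.25. In the model of the 8 exposed worms alone all 4 passed, with limma adjusted p of 0.034 (TA1-091629), 0.043 (TA2-179426), 0.026 (TA1-004780) and 0.026 (TA2-036519). TA1-202343 did not separate the exposures, with an EC50 vs EC10 change of 0.11 ± 0.18 (SE).

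Limma called 0 probes between EC50 and EC10, and 4041 probes (9.32%) had an unadjusted p under 0.05, 1898 higher and 2143 lower at EC50, against 5577 and 605 when centred on the spike-in transcripts. The change had one sign in all 4 blocks for 19.2% of the probes. A limma model of the 8 exposed worms alone called 211 probes, 8 higher and 203 lower at EC50, where the model of 12 worms called 0. Without control replicate 3, 168 probes were called, 159 of them lower. The unadjusted count was 2424 without EC50 replicate 1. Separate-channel worm means without the replicate block gave 2 calls, 12 arrays as replicates 3643 and 24 channels 7864. The EC10 and EC50 slide was scanned in a later session. Across probes, the EC50 vs EC10 change read directly on that slide correlated at 0.989 with the change read through the controls on the other slides. Within the slide that holds both groups, limma called 0 probes in each comparison, with 2288, 6272 and 3893 at an unadjusted p under 0.05 for EC10 vs control, EC50 vs control and EC50 vs EC10. TA1-202343 differed within its slides by 1.88 at EC10 and 1.98 at EC50 (log2).

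The changes at EC10 and EC50 against control were related across probes with a Pearson r of 0.41 and a Spearman rho of 0.40, with probes not being independent replicates. Both use the same 4 control worms. In 20 simulations of unchanged groups against shared controls r was 0.50 with a covariance of 0.0603, beside an observed covariance of 0.0649, a difference of 0.00458. The replicate blocks were also split 2 and 2 between the comparisons, so that each change rested on 2 exposed and 2 control worms. Then r ranged from -0.28 to 0.17 over the 6 splits, with a mean of 0.01, and the covariance averaged -0.00533. Fewer worms per change can also weaken r. A relation beyond the shared controls was thus not detectable over all probes. At an unadjusted p under 0.05, 455 probes were higher at both exposures and 397 were lower at both. Independent lists would share 65 and 69.1 probes, and unchanged groups against shared controls 267 and 272 in 5 simulations. Lists of unchanged groups are shorter, with 4.77% of the probes in the simulated EC50 vs control comparison where nothing had changed, against 12.4% measured at EC50. Longer lists share more probes, so these counts do not show a joint response beyond the shared controls. Opposite signs were found for 22 probes. The correlation was 0.62 without control replicate 3, 0.55 without control replicate 2 and 0.24 without EC10 replicate 1.

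**Figure D3:**
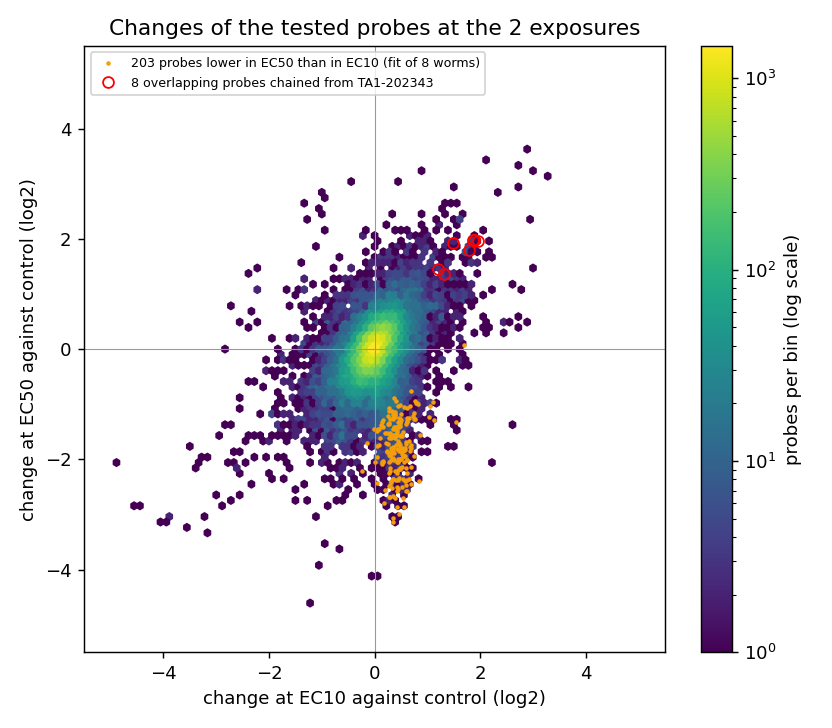
Log2 change at EC10 (horizontal axis) and at EC50 (vertical axis) against control for the 43347 tested probes, in bins coloured by the number of probes on a log scale. Red circles mark 8 overlapping probes that include TA1-202343, with changes of 1.2 to 1.95 at EC10 and 1.36 to 1.99 at EC50, and orange points mark the 203 probes lower at EC50 than at EC10 in the model of 8 worms.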

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

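The values below were compared after they had been seen. For 4 of the 10 named probes, the EC10 worms lay on one side of control and the EC50 worms on the other in all 4 replicate blocks. TA1-091629 differed by -2.21 at EC10 and 1.44 at EC50 (log2), an EC50 vs EC10 difference of 3.65. TA2-179426 differed by -0.68 and 0.63, a difference of 1.31. TA1-004780 differed by 1.06 and -1.02, a difference of -2.08, and TA2-036519 by 1.12 and -1.29, a difference of -2.41. For these 2 the size is uncertain, since they were dim at EC50 and processed signals gave differences of -3.35 and -3.46. The difference itself was tested in each case and had a limma adjusted p of 0.25, so it did not pass in the model of 12 worms. It passed for all 4 in the model of the 8 exposed worms, with limma adjusted p from 0.026 to 0.043, and for all but TA2-179426 without control replicate 3. These probes were named for their EC50 vs EC10 difference, which favours such a split. Over all tested probes, the order EC10 below control below EC50 held in all 4 blocks for 52 probes and the order EC50 below control below EC10 for 31, where chance gives 33.4 for each order.

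The spots for 10 spike-in transcripts, control RNAs of the array system that are not among the probes tested, gave the shift behind the spike-in centring above. The median probe, relative to the spike-ins, was 0.56 ± 0.40 (SD, n = 4) higher at EC50 than in control on the log2 scale, and higher in 4 of 4 blocks, from 0.16 to 1.09. The exact sign-flip permutation test over 4 blocks gave p = 0.125 (two-sided), the smallest it can give. The difference was 0.26 in the Cy3 blocks and 0.85 in the Cy5 blocks. At EC10 it was 0.22 ± 0.19 (SD, n = 4), higher in 3 of 4 blocks. In 39 groups of 4 worm values, of the named probes, the spike-ins and the sets of probes described further on, Dixon's gap test found none past its 95% critical value for 4 worms. For a group of 4 this takes a gap of most of the range, and control replicate 3, the lowest control in the set of 203 probes below, had a gap of 0.53 of the range in values relative to the block.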

How the results depend on the processing

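Limma called 0 probes in all 3 comparisons under the other background correction, Agilent's processed signals, median centring, scale normalization, both dim-probe filters, kept outlier spots, slide dye effects, the authors' value table, 1 value per sequence group (38899 groups) and the fits within a slide. Over the 8 of these that concern background, normalization, filter, outlier spots and the value table, the unadjusted counts ran from 2092 to 2195 at EC10, 5203 to 5480 at EC50 and 3820 to 4272 between the exposures. Calls (EC10, EC50, EC50 vs EC10) numbered 278, 5524 and 3643 with 12 arrays as replicates and 3642, 10180 and 7864 with 24 channels. Both count a worm more than once. The model of only the 2 groups compared called 0, 0 and 211, and spike-in centring, added after the data were seen, 0, 80 and 0. The cause was not tested for these 2.

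Separate-channel worm means gave 4, 25 and 2 calls with no replicate block and 0, 0 and 0 with the replicate block. Worms of one number did not deviate together. Their correlations ran from -0.17 to 0.25, and 3 of 12 worms correlated best with their own number. The block comes from the hybridisation layout. Leaving out each worm in turn gave 0 to 3, 0 to 379 and 0 to 168 calls. All calls came without control replicate 3. The correlation of the EC10 and EC50 changes ran from 0.24 to 0.62 with a worm left out and from 0.39 to 0.44 under the 14 other settings. The technical SD was 0.0543 without background correction. No named probe changed direction in the 334 values computed, of which 41 passed the threshold (24 with arrays or channels as replicates, 17 with worms), but some sizes varied: processed signals gave -3.35 for TA1-004780 and -3.46 for TA2-036519 (EC50 vs EC10), and spike-in centring -0.78 for TA1-125379 and -0.61 for TA1-011406 (EC50 vs control). TA1-004780 and TA2-036519 have none with only probes above background on all readings, and no named probe has one per sequence group. Set tests on gene lists and 1 probe per gene could not be run without gene names. Dimness limits the sizes given for TA1-004780 and TA2-036519.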

Other observations

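The sets of probes in this part were chosen after their values had been seen, and so were the tests on them, except the share of small p-values over all other groupings. A set of 203 probes moved together. They were the probes lower at EC50 than at EC10 in the model of the 8 exposed worms, which held no control values. The worm values in it were solved from whole loops, arrays with control worms included. The level of a control worm cancels there, but the hybridisation error of its arrays does not. The EC50 minus EC10 difference of the set's median ran from -2.67 to -1.83 (log2) in the 4 blocks, which also chose the probes. Over 203 probes chosen again without the block that was read, the median difference ran from -2.87 to -1.63. Against control, the EC50 worms were lower in 4 of 4 blocks, with a mean difference of -1.78 ± 1.23 (SD, n = 4), but the difference in the block of replicate 3 was -0.15. The choice of probes low in these same EC50 worms favours such a drop. The EC10 worms were higher than control in 2 of 4 blocks. No probe of the set passed in the model of 12 worms. TA2-204323, the member with the smallest p among the 8 worms, differed by -3.17 ± 0.71 (SE) between EC50 and EC10 and by -2.58 ± 0.71 (SE) between EC50 and control, with limma adjusted p of 0.36 and 0.28. TA1-004780 and TA2-036519 belong to the set.

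In separate-channel log2 intensities, which compare worms across blocks but carry dye differences, control replicate 3 had a set median of 7.80, near the EC50 worms' 7.22 to 8.43, while the other controls lay at 9.48 to 11.31. Whether that worm was exchanged with the EC50 worm of its block, at 7.7, cannot be decided from this set. For each block, 203 probes were chosen again by the EC10 and EC50 worms of the other 3 blocks, with no control values in the model. In this block the EC50 worm minus control replicate 3 was -0.32 (quartiles -0.66 and 0.30). The other blocks, each over its own 203 probes, gave -3.01, -1.56 and -2.07. An exchange would turn the sign, but both worms of this block were low. Turned or not, the difference would be smaller in size than in the other blocks. An exchange would also still leave a low control. The choice used values solved from whole loops, so arrays with control replicate 3 entered it. The level of that worm cancels there, but the hybridisation error of its arrays does not. Of 100 probes chosen by their EC50 vs control p in the other 3 blocks, 79 had the same direction in this block. The blocks of numbers 1, 2 and 4, read likewise, gave 72, 69 and 69. An exchange would turn these directions, so the 79 probes argue against it. Over all probes, the 2 changes had a correlation of 0.05 in this block, against 0.41, 0.23 and 0.34 in the others. That correlation sets this block apart and does not tell on an exchange. Hybridisation error is argued against by a loop-closure SD of 0.12 (log2) over the set in the loop of that worm. It does not see a fault in the amplification or labelling of a worm's RNA, which stays open. In these intensities, pairs of probes of the set had a median correlation of 0.98 over the 4 control worms. Among 1000 sets of probes matched on their SD over the control worms the highest was 0.32, but sets matched on their EC50 vs EC10 change in the 8 exposed worms had a median of 0.78 and reached 0.90, so much of the correlation goes with a large drop at EC50. The match on change was loose, with a median change of -1.96 against -2.16 and 136 probes per set from a pool of 471. A group of transcripts that rises and falls together between worms of one group is a hypothesis for this set. An effect of the exposure on it stays open, and which tissue or state it follows was not tested.

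The overlapping probes form a second pattern. Starting from TA1-202343, probes were chained if they shared an ungapped overlap of at least 18 bases with at most 15% mismatches, by sequence alone. The chain held 8 probes. Their mean was 1.67 ± 0.57 (SD, n = 4) higher at EC10 and 1.81 ± 0.28 (SD, n = 4) higher at EC50 than in control (log2), 3.19-fold and 3.49-fold. The EC50 minus EC10 difference was 0.13, with a 95% interval of -0.39 to 0.66 over the 4 blocks. A chain member, TA1-009720 (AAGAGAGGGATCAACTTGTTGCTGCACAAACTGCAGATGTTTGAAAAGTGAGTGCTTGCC), has a forward reading frame with no stop codon that reads 6 cysteines among 19 residues. Of the 20 probes with the smallest p at EC50, 6 belong to this chain and 19 were higher at EC50 than in control, 11 of them above 1.5 (log2) at both exposures.

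Some other explanations for the chain were examined. A constant dye bias of a probe cancels from these changes by design, because the worms compared within a block carried the same dye. The lowest mean change of the blocks of one dye was 1.56, which is therefore no test of such a bias. A fault of one probe would leave the others flat, but the lowest change in the chain was 1.20. A general rise of cysteine-rich transcripts is not seen either: 220 other probes with at least 5 cysteines in an open forward frame had an upper quartile of 0.17 at EC50. What stays open is that all 8 probes read the same 12 worms, so they add no replicates, and near-identical gene copies could share the signal. A response of the transcript read by this chain to the compound at both concentrations is a hypothesis. It did not pass the multiple-test threshold and need not be particular to this chain.

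Other groupings of the worms were compared with the real one. Worm values are relative to their block, so only the 8 splits with 1 worm of each group per block have the form of the real split, and 8 are too few for a share under 0.05. For probes past the limma threshold the real value was 0 in each comparison, so 8 of 8 splits gave as many by necessity, which bears on nothing. The highest other split gave 1 at EC10, 0 at EC50 and 1 between the exposures. For unadjusted p under 0.05, 6 of 8 splits gave at least the real 2166 at EC10 (highest other 4273), 1 of 8 gave at least the real 5365 at EC50 (highest other 3677) and 2 of 8 gave at least the real 4041 between the exposures (highest other 4239). Over all 35 splits, which also mix the groups unevenly over the blocks, the highest others were 6468, 6790 and 4875.

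With 12 arrays as replicates, 1 of the 8 splits, the real one, reached its 278 calls at EC10 (highest other 41), its 5524 at EC50 (highest other 4) and its 3643 between the exposures (highest other 39). Again 8 splits are too few for a share under 0.05. Over all 35 splits the highest others were 1388, 3028 and 2118. In the other 34 splits at EC10, the array model gave a median of 11.9% of probes with an unadjusted p under 0.05, against 16.1% for the real split. In the 7 others of the real form the median was 9.18%, from 2.15% to 14.9%. Values above 5% are expected where arrays that share worms understate the spread between worms.

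The order control below EC10 below EC50 held in all 4 blocks for 157 probes and the reverse order for 73, where chance gives 33.4 each if probes were independent. The probes are not independent, and no test was made of this excess.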
